A study of Mus musculus with 6 samples.

How the data were processed

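RNA was measured in 6 libraries of sorted nuclei from the medial prefrontal cortex (mPFC) of Foxp2-Cre mice, 3 from animals in the CFA condition and 3 from saline controls. Per the labels, the nuclei carried GFP fused to a KASH domain, which anchors a protein in the nuclear envelope, and were collected 4 weeks after bilateral injection of the virus that delivers it. Per the labels' protocols, 10000 nuclei went into each library, polyadenylated RNA was converted to cDNA with the Smart-seq V4 kit and 9 PCR cycles, and 300 ng of cDNA entered the Nextera XT library preparation. Neither kit marks the strand of the transcript, so reads of a gene and of an overlapping antisense gene cannot be told apart. Groups and replicate numbers were taken from the sample titles. The labels do not say when CFA or saline was given relative to collection.

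The deposited table held raw counts per gene for 24421 genes, 1 column per library, with the exon intervals, strand and exon length of each gene model, per the file headers. Per the submitters' processing notes, the tools behind these counts were Trim Galore, HISAT2 2.2.1, SAMtools 1.13, featureCounts 2.0.1 and edgeR 3.32.1, and the genome build was mm10. The settings for strand and for reads that map to several places are not given in the sources used here. Reads of near-identical family members, such as the MHC class I genes, the Ifit genes and the guanylate-binding proteins, may therefore have been divided or dropped, and their values are uncertain to that extent. Symbols of 27 genes had been turned into dates in the table and were restored by matching their exon ends to the GENCODE annotation of the same build. The table held no mitochondrially encoded gene. Of 102 genes looked at (the named genes and the interferon-stimulated genes), 8 shared exon sequence with another gene model in the table: Cox6a2, Gpr17, H2-D1, Ifi27, Lypd1, Srebf1, Tada2b and Tmem255a. For H2-D1 the other gene lay on the same strand, and for the rest on the opposite strand.

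Total counts ranged from 9673038 to 11850741 per library. A count of 3, the upper limit that a count of 0 allows, corresponded to 0.25 to 0.304 CPM (library-scaled counts), and such floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 17 or more, so no library was counted as a copy of another. The common biological coefficient of variation was 26.8%.

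Genes were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts with TMM normalization, the default filterByExpr filter and Benjamini-Hochberg adjustment over the 13560 genes tested, with a threshold of 0.05. Treatment was the only term of the model, and log2 fold changes are CFA minus saline. Standard errors were derived from the quasi-likelihood F statistic. CPM values were scaled by the TMM factors, and log2 CPM used a prior count of 2.

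Before the data were examined, 33 gene lists were fixed, covering activity-regulated genes, ion channels, receptors, synapse, stress, inflammation, interferon, metabolism, chromatin and the cell types that such a sort might hold. Of these, 32 had at least 5 tested members. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists, and again with a correlation estimated per list and with the rotation test fry. The level of a list in a library is the mean log2 CPM of its members, and levels were compared with a two-sided exact permutation test, for which 3 against 3 libraries cannot give a p below 0.1. Ranges of a list's median are bootstrap bounds over its members, and the spread of a level between libraries is a Welch t interval. The list of mitochondrially encoded genes was not tested. Scn2a and Ccn2 were found under their older symbols Scn2a1 and Ctgf.

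The rule for named genes was also fixed before the data were examined. It took Foxp2, Slc17a7, Gad1 and Gad2, then called genes with a mean log2 CPM of at least 2, no overlap between the groups and an ordinary symbol. Where fewer than 10 genes were called, it took the 10 genes with the smallest p in each direction under the same filters, as values and not as calls. From each list without a called member it took the 2 members with the smallest p. For the check of the sort, the most abundant markers of each other cell class were fixed before in the same way. Other genes outside this rule are marked in the text as chosen after their values were seen. A few genes that were looked at are not reported here.

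Alternatives covered RLE and library-size scaling, removal of ribosomal protein genes, no low-count filter and a filter of at least 5 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, a threshold of 0.1, a minimum log2 fold change of 1, offsets that remove a gene-length trend (loess with a span of 0.5), the replicate number as a block, and leaving out each library in turn. The scripts were tested on 5 simulated data sets with the means and library sizes of this comparison, 13560 genes and 200 changed genes each. There, 47.2% of the genes with a log2 change of 1 and 83.2% of those with a log2 change of 2 were called, and 6.86% of the calls were unchanged genes. A simulated list of 20 genes with a log2 change of 1 was called in 5 of 5 simulations, and 4% of unchanged lists had an unadjusted camera p under 0.05. Simulated genes vary independently, so this test does not cover lists whose members vary together or libraries with a structure other than treatment. The shares of genes called there may therefore not hold for these libraries.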

Results

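Gene expression was measured in Foxp2-positive neurons of the medial prefrontal cortex (mPFC) of mice treated with CFA (complete Freund's adjuvant, an inflammatory agent used to produce lasting pain) or with saline. Foxp2 is a transcription factor that marks corticothalamic neurons of the deep cortical layers. Nuclei were labelled in Foxp2-Cre mice by a virus expressing GFP with a KASH domain and were sorted before RNA sequencing, with 3 libraries per group. Total counts were 11850741, 11250924 and 10663201 in the CFA libraries and 11104887, 11117681 and 9673038 in the saline libraries, with 15734 to 16075 and 15268 to 15848 genes detected. The labels name replicates but do not say whether each came from a separate animal, so p-values of the gene and permutation tests measure the spread between these libraries, which may be partly technical. Camera compares the members of a list with the other genes. Its p with the preset correlation of 0.01 rests on that assumed value and does not measure the spread of a list's level between libraries. Unless stated otherwise, expression is given as mean CPM ± SD over the 3 libraries of a group.

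The main excitatory marker was far above the inhibitory markers in both groups. Slc17a7, which encodes the cortical vesicular glutamate transporter, was at 2280 ± 357 CPM in CFA and 2140 ± 177 CPM in saline libraries. Foxp2 was at 29.2 ± 5.50 and 33.8 ± 8.61 CPM, a log2 fold change of -0.21 ± 0.24 (SE). The enzymes of GABA synthesis were far lower than Slc17a7, though Gad1 was above Foxp2, with Gad1 at 64.9 ± 18.8 and 60.2 ± 12.4 CPM and Gad2 at 22.3 ± 8.57 and 19.0 ± 6.91 CPM. These differences between groups were smaller than the spread between libraries. As lists, corticothalamic markers had a mean log2 CPM of 6.49 in CFA and 6.63 in saline libraries. Upper layer and intratelencephalic markers were at 4.19 and 4.22, but lists of different genes have no common baseline. Among the abundant layer markers, Crym and Lamp5 were at similar levels. Crym, in the corticothalamic and layer 5 lists, was at 259 ± 28.6 and 301 ± 56.5 CPM. Lamp5, in the upper layer and intratelencephalic list, was at 287 ± 16.5 and 239 ± 34.2 CPM. Without an unsorted sample, enrichment of deep-layer neurons could not be measured. Transcripts of other cell types were present in all libraries. Slc1a2, an astrocyte glutamate transporter also transcribed in neurons, was at 307 ± 52.9 and 323 ± 39.4 CPM, and Mbp, a myelin protein, was at 166 ± 31.4 and 152 ± 6.49 CPM. Rgs5, a pericyte marker, was at 2.70 ± 1.41 and 2.97 ± 0.449 CPM.

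The libraries did not separate by treatment along the main axis of variation. The first principal component held 27.9% of the variance and set saline replicate 3 (-50.4) against saline replicates 1 and 2 (29.9 and 35.8), with the CFA libraries between -19 and 4.19. The third component, with 19.7% of the variance, did separate the groups, with CFA libraries at -10, -40.1 and -15 and saline libraries at 30.6, 9.29 and 25.3, where chance gives 10% for any 1 component. Correlations of log2 CPM across genes, which are not independent replicates, were 0.955 to 0.968 within CFA, 0.935 to 0.947 within saline and 0.943 to 0.957 between groups. Saline replicate 3 had the largest shares of the long non-coding RNAs Malat1 (2.77%, against 1.36% to 2.2% elsewhere), Meg3 (0.775%, against 0.244% to 0.486%) and Snhg11 (1.06%, against 0.416% to 0.702%). It also had the lowest level of cytoplasm-rich neuronal transcripts, a mean log2 CPM of 9.02 against 9.30 to 9.60 in the other 5 libraries.

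The comparison of CFA with saline libraries asked which transcripts of these neurons differ between mice given CFA and controls. No single gene passed the threshold. Of 13560 genes tested, 0 had an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.91. At an unadjusted p under 0.05 there were 437 genes, 183 higher and 254 lower in CFA, where 678 would be found by chance. The CFA and saline values did not overlap for 1019 genes, 7.51% of those tested, where chance gives 10% for 3 against 3. Other tools called few genes: limma-voom called 0 (469 at an unadjusted p under 0.05), DESeq2 called 8 (5 higher, 3 lower) and edgeR's likelihood ratio test called 11 (7 higher, 4 lower). Without saline replicate 3 the quasi-likelihood test called 5 genes, all lower in CFA, and without a filter on low counts it called 9.

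The genes with the smallest p that were higher in CFA are given as values, not as calls. Samd9l, an interferon-induced antiviral gene (chromosome 6, 3372258 to 3399571, mm10), was at 27.3 ± 6.11 CPM in CFA and 8.52 ± 4.44 CPM in saline libraries, a log2 fold change of 1.68 ± 0.37 (SE). Ifit1, which encodes a cytosolic sensor of viral RNA (chromosome 19, 34640889 to 34650009), was at 50.0 ± 48.3 and 5.03 ± 5.40 CPM, a log2 fold change of 3.30 ± 0.83. Its spread in CFA came mostly from replicate 3, at 106 CPM against 22.9 and 21.3 CPM. Irf7, a transcription factor of the interferon response (chromosome 7, 141263183 to 141266424), was at 10.8 ± 5.97 and 2.15 ± 1.38 CPM. Tap2, a subunit of the peptide transporter for MHC class I loading (chromosome 17, 34204479 to 34216321), was at 12.9 ± 3.29 and 4.74 ± 0.723 CPM. The MHC class I gene H2-T23 was at 71.9 ± 19.5 and 40.5 ± 1.87 CPM, and Gbp7, an interferon-induced GTPase, was at 9.12 ± 7.43 and 2.77 ± 0.152 CPM. Gbp7 too was highest in CFA replicate 3, at 17.7 CPM against 5.07 and 4.59 CPM in CFA replicates 1 and 2. Enpp2, the enzyme that makes lysophosphatidic acid, had a log2 fold change of 0.72 ± 0.17, with 148 ± 12.1 and 89.7 ± 10.4 CPM. Srebf1, a transcription factor of lipid synthesis, Fam43a and Specc1l had log2 fold changes of 1.27, 1.68 and 0.68. Unadjusted p-values of these 10 genes ran from 0.000412 (Samd9l) to 0.00723 (Gbp7) in edgeR's quasi-likelihood test.

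Among the genes with the smallest p that were lower in CFA, Heca (chromosome 10, 17900466 to 17948067) had the smallest of all, an unadjusted p of 8.17e-05 in edgeR's quasi-likelihood test. It was at 3.40 ± 1.14 CPM in CFA and 16.0 ± 6.15 CPM in saline libraries, a log2 fold change of -2.24 ± 0.41 (SE). Qk, an RNA-binding regulator of splicing (chromosome 17, 10206471 to 10319361), was at 26.5 ± 5.59 and 61.4 ± 18.1 CPM, a log2 fold change of -1.21 ± 0.25. Tmem255a, a transmembrane protein (chromosome X, 38196573 to 38252481), was at 11.4 ± 3.54 and 32.3 ± 10.1 CPM, and part of its exon sequence overlaps Zbtb33 on the opposite strand. Nrp2, a semaphorin co-receptor (chromosome 1, 62703317 to 62818692), was at 19.7 ± 5.23 and 39.9 ± 1.44 CPM, a log2 fold change of -1.02 ± 0.24. Tada2b and Brd1, subunits of histone acetyltransferase complexes, had log2 fold changes of -1.25 and -0.95. Gdpd2, Lnpep, Rbm41 and Egfem1 had log2 fold changes of -1.32, -1.30, -1.38 and -0.88. DESeq2 called Heca, Qk and Tmem255a lower, with adjusted p-values of 0.00471, 0.0275 and 0.0212, and Samd9l higher, with an adjusted p of 0.0374.

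**Figure D1:**
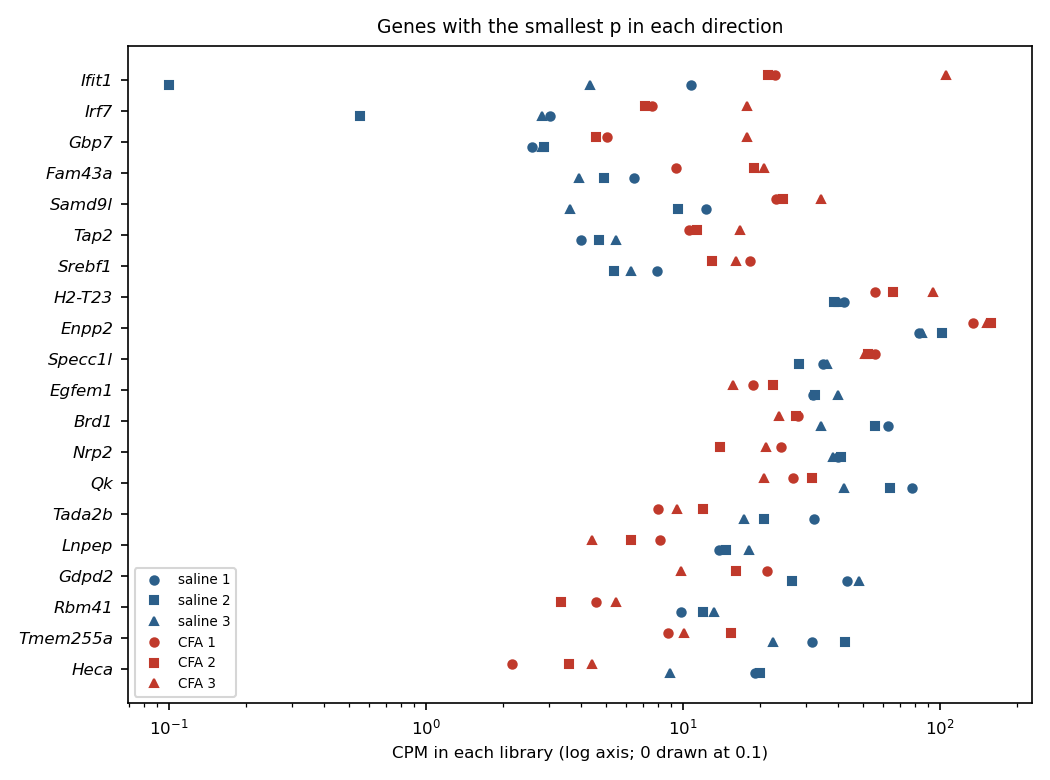
CPM (log axis, a count of 0 drawn at 0.1) of the 10 genes with the smallest p in each direction, 1 symbol per library, CFA in red and saline in blue. The groups do not overlap for these genes because the rule that chose them required it, and none passed the adjusted threshold in edgeR's quasi-likelihood test.

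Among gene groups, interferon-stimulated genes, microglia markers and astrocyte markers were higher in CFA as lists, and striatal projection neuron markers and layer 6b neuron markers were lower. These 5 of 32 lists passed camera with a preset correlation and Benjamini-Hochberg adjustment. With a correlation estimated per list 0 lists passed (adjusted p = 0.654 or more), and 0 passed fry. The levels of 4 of the 5 lists overlapped between groups (p = 0.2 in a two-sided exact permutation test), all but the interferon list. It was the only list of the 32 without overlap, where chance gives 10% for any 1 list at 3 against 3. Without saline replicate 1, 17 lists passed camera, and with a filter of at least 5 CPM in at least 3 libraries 3 did.

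**Figure D2:**
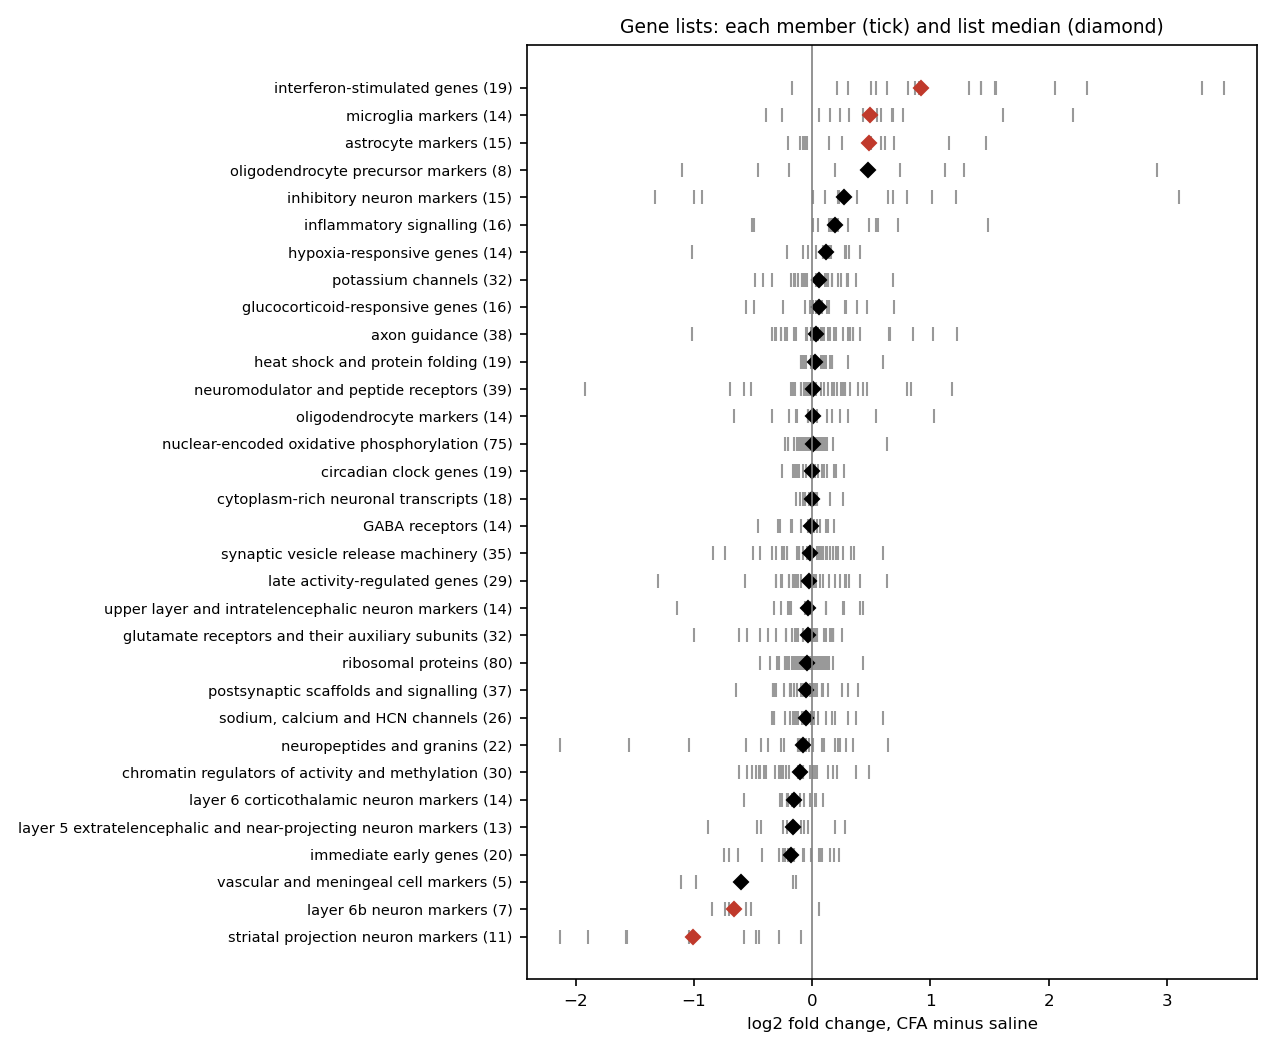
Log2 fold change (CFA minus saline) of each tested member (grey tick) of the 32 gene lists and the median of each list (diamond), with the number of tested members in parentheses. Red diamonds are the 5 lists that passed camera with a preset correlation, with medians of 0.92, 0.49, 0.48, -0.66 and -1.01, and none of the 32 passed with an estimated correlation.

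Interferon-stimulated genes were the list with the largest positive median. Of 19 tested members 18 had a positive log2 fold change, with a median of 0.92 and a mean of 1.26. Oasl2, an antiviral oligoadenylate synthetase-like protein, was at 15.7 ± 10.0 CPM in CFA and 1.40 ± 1.21 CPM in saline libraries, a log2 fold change of 3.48 ± 0.76 (SE), and Ifit1 and Irf7 are given above. Irf1, a transcription factor of the interferon response, was at 13.6 ± 1.89 and 7.46 ± 0.339 CPM. Over all genes 0 members were called, and adjusted over the list alone 5 were, all higher, among them Oasl2, Ifit1, Irf7 and Irf1 (Irf1 was chosen after its values were seen). Ifi27, also chosen after its values were seen, was the exception, at 75.9 ± 3.53 and 85.3 ± 12.9 CPM.

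The list passed camera with an adjusted p of 2.88e-09 with the preset correlation. The adjusted p was 0.654 with the estimated correlation of 0.481 (unadjusted p = 0.0858) and 0.78 in fry. The mean log2 CPM of the list was 3.24, 3.40 and 4.33 in the CFA libraries and 3.06, 0.99 and 2.78 in the saline libraries, so that the groups did not overlap (p = 0.1 in a two-sided exact permutation test, the smallest that 3 against 3 allows). Saline replicate 2 was thus far below the others, with 0 counts of Ifit1 and of Oasl2. The median was 0.77 without that library and 1.56 without saline replicate 1. Microglia and astrocyte markers were higher in the same group, with medians of 0.49 and 0.48, and the level of microglia markers was also lowest in saline replicate 2, at a mean log2 CPM of 1.38 against 2.11 to 2.88. In CFA replicate 3, where the interferon level was highest, the levels went apart. Its microglia level was 2.11, against 2.55 and 2.11 in saline replicates 1 and 3. Its astrocyte level of 3.70 was the lowest of the CFA libraries (4.18 and 4.26 in replicates 1 and 2).

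**Figure D3:**
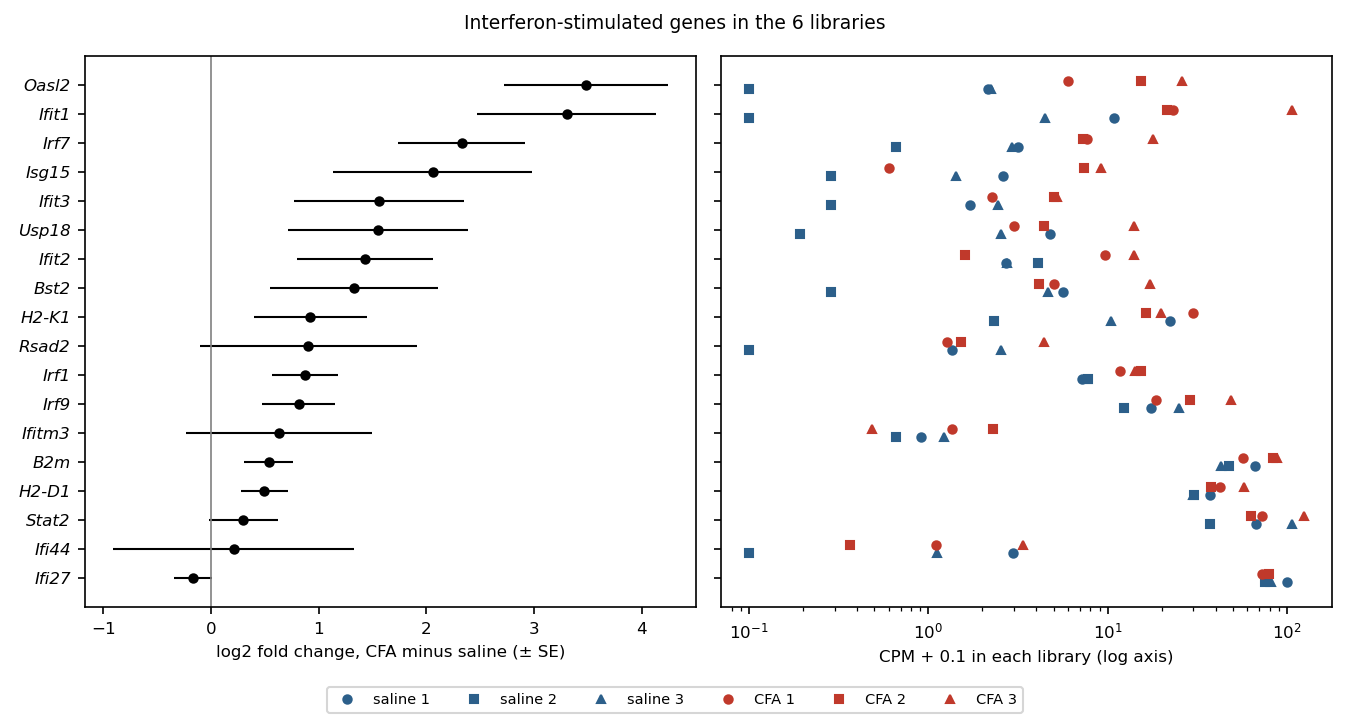
Left, log2 fold change (CFA minus saline, bars are SE) of 18 of the 19 tested interferon-stimulated genes. Right, CPM + 0.1 of each gene in each library on a log axis, where saline replicate 2 (blue squares) is lowest for many genes and CFA replicate 3 (red triangles) is at 106 CPM of Ifit1 against 0 to 22.9 CPM in the other libraries.

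Striatal projection neuron markers were lower in CFA as a list, with all 11 tested members negative and a median log2 fold change of -1.01. Penk, which encodes proenkephalin, the precursor of opioid peptides, was at 30.5 ± 41.2 CPM in CFA and 134 ± 151 CPM in saline libraries. The retinoic acid receptor Rarb was at 6.48 ± 1.47 and 13.0 ± 4.98 CPM and the dopamine receptor Drd1 at 84.6 ± 18.9 and 126 ± 27.8 CPM. Penk was highest in saline replicate 1, at 308 CPM, and was at 78.1 CPM in CFA replicate 1. The list passed camera with an adjusted p of 9.39e-06 with the preset correlation, against an adjusted p of 0.654 with the estimated correlation of 0.622. Over all genes and adjusted over the list alone 0 members were called, and the levels overlapped (p = 0.2 in a two-sided exact permutation test). The median was -0.36 without saline replicate 1 and -0.575 with a filter of at least 5 CPM in at least 3 libraries.

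Layer 6b markers, of the deepest cortical neurons, were lower in CFA as a list, with 6 of 7 members negative and a median of -0.66. Ctgf, which encodes a secreted matrix protein, was at 126 ± 31.0 CPM in CFA and 200 ± 54.0 CPM in saline libraries, a log2 fold change of -0.66 ± 0.22 (SE), and the hormone precursor Trh was at 10.3 ± 0.365 and 15.2 ± 3.77 CPM. The adjusted p of this list was 0.00304 in camera with the preset correlation and 0.654 with an estimated correlation. The call was lost without CFA replicate 2 (median -0.42) and without saline replicate 2 (median -0.42). Adjusted over the list alone 0 members were called, as over all genes. Layer 6 corticothalamic markers, the class that Foxp2 marks, did not pass: 11 of 14 members were negative, with a median of -0.16 and a camera adjusted p of 0.102. Ntsr1, a neurotensin receptor of corticothalamic neurons, was at 14.0 ± 2.11 and 21.0 ± 2.06 CPM, and Hs3st4 was at 57.9 ± 5.22 and 70.0 ± 9.66 CPM. Neither upper layer and intratelencephalic markers (median -0.035) nor layer 5 extratelencephalic and near-projecting markers (median -0.16) passed. Without saline replicate 1 corticothalamic (-0.19) and layer 5 markers (-0.18) passed as lower, but the medians were -0.044 for corticothalamic markers without saline replicate 2 and -0.074 for layer 5 markers without CFA replicate 2.

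Among glial lists, astrocyte markers were higher in CFA as a list, with 10 of 15 members positive and a median of 0.48. Aldoc, a glycolytic enzyme of astrocytes, was at 176 ± 30.0 CPM in CFA and 125 ± 14.1 CPM in saline libraries, and the growth factor receptor Fgfr3 was at 5.84 ± 2.01 and 2.09 ± 1.22 CPM. Microglia markers were also higher as a list, with 12 of 14 members positive and a median of 0.49. Csf1r, the receptor for colony stimulating factor, was at 11.8 ± 5.91 and 3.83 ± 3.16 CPM, and Itgam was at 1.55 ± 1.01 and 0.338 ± 0.585 CPM. In camera the adjusted p was 0.00077 for astrocytes and 0.00304 for microglia with the preset correlation, and with an estimated correlation the adjusted p was 0.654 and 0.665. Over all genes and adjusted over each list alone 0 members of either list were called.

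The astrocyte call was lost without CFA replicate 2 (median 0.36), and the median was 0.25 without CFA replicate 1 and 0.30 without saline replicate 2. The microglia call was lost with a filter of at least 5 CPM in at least 3 libraries (9 members left) and without CFA replicate 1, CFA replicate 2, saline replicate 2 or saline replicate 3 (medians 0.42, 0.28, 0.32 and 0.41), while the median was 0.87 without saline replicate 1. Oligodendrocyte precursor markers had a median of 0.47 and did not pass (camera adjusted p of 0.102). Of their 8 members Gpr17 was called when adjusted over the list alone (adjusted p of 0.0462 in edgeR's quasi-likelihood test), at 4.00 ± 1.38 and 0.514 ± 0.493 CPM, and Olig1 was at 20.7 ± 3.11 and 12.4 ± 1.81 CPM. Oligodendrocyte markers had a median of 0.0045, vascular and meningeal markers a median of -0.60 over 5 tested members, and inhibitory neuron markers a median of 0.27, and none of these passed with all libraries and treatment as the only term. Without saline replicate 1, oligodendrocyte precursor (0.82), oligodendrocyte (0.20) and inhibitory neuron markers (0.56) passed as higher, but medians were -0.20 for oligodendrocyte and -0.018 for inhibitory markers without CFA replicate 1 and 0.27 for precursor markers without CFA replicate 2. Precursor markers also passed without saline replicate 2 (0.77), inhibitory markers without CFA replicate 3 (0.495) and vascular markers, as lower, without CFA replicate 1 (-1.15). With the level of striatal markers as a covariate, chosen after the data were seen, precursor (0.725), oligodendrocyte (0.28) and inhibitory markers (0.71) passed as higher, and with the level of microglia markers as a covariate, also chosen then, oligodendrocyte markers passed as lower (-0.37).

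**Figure D4:**
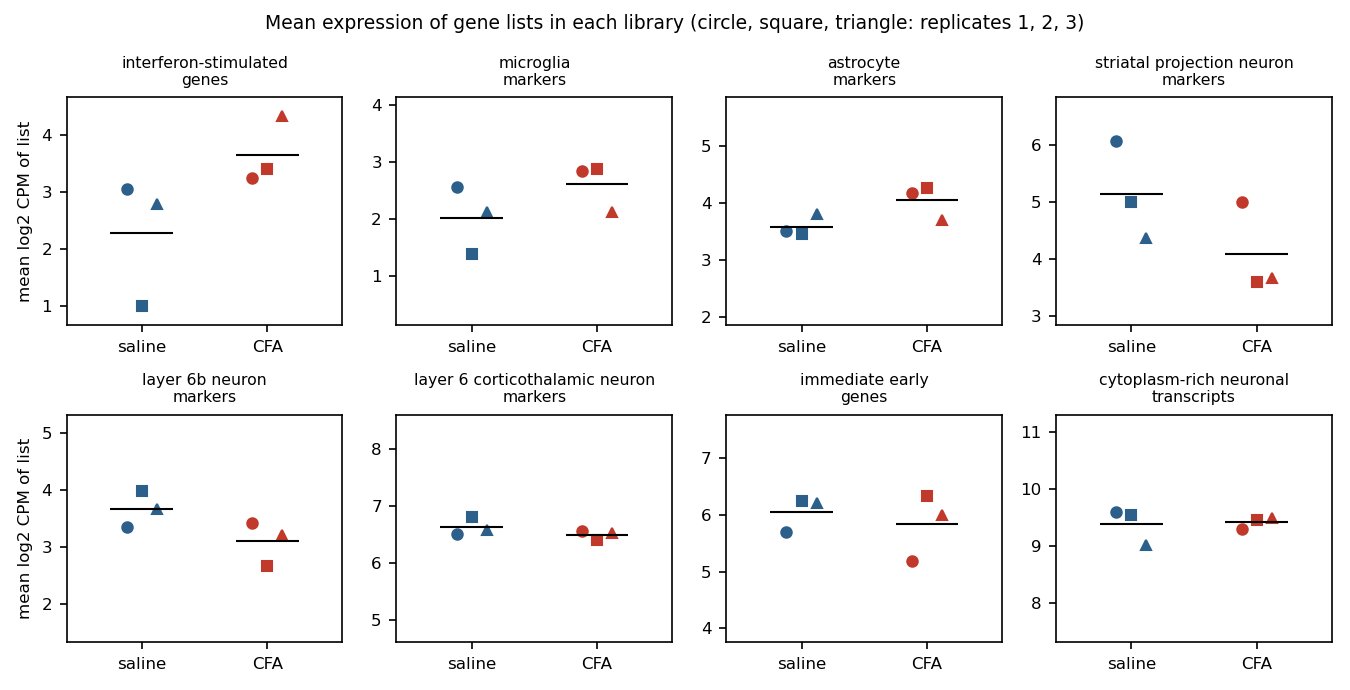
Mean log2 CPM of 8 gene lists in each library (circle, square and triangle are replicates 1, 2 and 3, the line is the group mean, and each panel spans 4 log2 units). The interferon list separates the groups, with 3.24 to 4.33 in CFA and 0.99 to 3.06 in saline libraries. Chance alone separates 3 against 3 libraries in 10% of lists. The striatal list overlaps between groups, and cytoplasm-rich transcripts are lowest in saline replicate 3.

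Transcripts induced by neuronal activity did not pass the list test with all libraries and treatment as the only term. The time between treatment and collection is not given in the labels. Immediate early genes had a median log2 fold change of -0.18 over 20 members, with 14 negative. Nr4a2, which also belongs to the layer 6b list, and Nr4a3 were the members with the smallest p. They were at 17.9 ± 9.96 and 14.1 ± 1.89 CPM in CFA against 29.1 ± 15.8 and 21.8 ± 12.2 CPM in saline libraries. The camera adjusted p of the immediate early list was 0.102, and its level varied within CFA from 5.19 to 6.32 (mean log2 CPM). The list passed camera as lower without CFA replicate 2 (median -0.45) and without saline replicate 1 (median -0.30), and its median was 0.11 without CFA replicate 1. With all libraries it also passed as lower with the replicate number as a block (-0.16), with block and length offsets (-0.20) and with the level of striatal markers as a covariate (-0.69), which was chosen after the data were seen. Late activity-regulated genes had a median of -0.031, with Rgs4 at 573 ± 39.4 and 462 ± 107 CPM and Nptx2 at 35.1 ± 6.93 and 26.4 ± 8.71 CPM. Neuropeptides and granins had a median of -0.076 and did not pass. Penk and Tac1 were their members with the smallest p, and both also belong to the striatal list. Tac1, the substance P precursor, was at 11.9 ± 4.88 and 24.5 ± 20.9 CPM.

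Genes that set excitability and synaptic transmission did not pass the list test with all libraries and treatment as the only term either. Potassium channels had a median of 0.060 and sodium, calcium and HCN channels a median of -0.056. Kcnc2, a fast delayed rectifier, was at 28.4 ± 4.10 CPM in CFA and 17.7 ± 0.532 CPM in saline libraries, a log2 fold change of 0.68 ± 0.23 (SE). Glutamate receptors had a median of -0.037 and GABA receptors a median of -0.0091, with the kainate receptor Grik1 at 6.64 ± 2.05 and 13.3 ± 4.36 CPM and Gabra2 at 28.9 ± 4.65 and 39.7 ± 9.75 CPM. Neuromodulator and peptide receptors had a median of 0.0048. Of these, the serotonin receptor Htr2a was at 16.1 ± 1.40 and 9.02 ± 2.68 CPM. Postsynaptic scaffolds had a median of -0.054. The synaptic vesicle release machinery had a median of -0.015 and a mean of -0.044, whereas camera placed it on the higher side with an adjusted p of 0.96. Axon guidance genes had a median of 0.030, and of their 38 members Nrp2 was called when adjusted over the list alone (adjusted p of 0.0282 in edgeR's quasi-likelihood test). Without saline replicate 1, sodium, calcium and HCN channels (median -0.16) and postsynaptic scaffolds (median -0.14) passed camera as lower, but their medians were 0.074 and 0.042 without saline replicate 3. With the level of microglia markers as a covariate, chosen after the data were seen, neuromodulator receptors (median 0.20) passed as higher. None of the members of the other lists in this paragraph was called, over all genes or adjusted over the list alone.

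Stress, metabolic and regulatory lists likewise did not pass camera with all libraries and treatment as the only term. Inflammatory signalling genes had 14 of 16 members positive, with a median of 0.19 and an adjusted p of 0.102. Il6st, the shared receptor subunit of the interleukin 6 family, was at 47.7 ± 11.3 CPM in CFA and 32.4 ± 6.48 CPM in saline libraries. Chromatin regulators had a median of -0.10, also with an adjusted p of 0.102, and the histone deacetylase Hdac4 was at 43.6 ± 7.39 and 63.7 ± 7.02 CPM. Medians were 0.12 for hypoxia-responsive genes, 0.059 for glucocorticoid-responsive genes, 0.022 for heat shock and protein folding, and 6.1e-05 for circadian clock genes. Ribosomal proteins (80 members) and nuclear-encoded oxidative phosphorylation (75 members) had medians of -0.041 and 0.0035. These depended on single libraries. Without saline replicate 1, oxidative phosphorylation (median 0.23), ribosomal proteins (0.21) and heat shock genes (0.16) passed as higher and chromatin regulators (-0.23) as lower. Chromatin regulators also passed as lower (-0.185) and oxidative phosphorylation as higher (0.11) without CFA replicate 1. Ribosomal proteins passed as lower without CFA replicate 2 (-0.16) and saline replicate 3 (-0.14), and oxidative phosphorylation (-0.16) and cytoplasm-rich transcripts (-0.18) as lower without saline replicate 3. With the microglia covariate ribosomal proteins passed as lower (-0.22). Cytoplasm-rich neuronal transcripts had a median of -0.0035 and a mean of 0.0024. Camera adjusted p-values of the 27 lists that did not pass ranged from 0.102 to 0.96 with the preset correlation, and with an estimated correlation from 0.654 to 0.982.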

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

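Covariates of marker levels were added after the data were seen, and the other settings were fixed before. The count of called genes was 0 under RLE and library-size scaling, without ribosomal protein genes, with at least 5 CPM in 3 libraries, in limma-voom, with gene length offsets, at an adjusted p of 0.1 and with either covariate. It was 9 without a low-count filter (18084 genes tested, 745 at an unadjusted p under 0.05), 8 in DESeq2, 11 in the likelihood ratio test, and 0 to 5 when 1 library was left out (5 without saline replicate 3). The cause was not tested. Of 1620 alternative values of the 86 named genes, 18 in 11 genes had the other sign. Library sizes put 3 counts at 0.25 to 0.304 CPM, so a gene at 0 in a single library is known only to that level.

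With the replicate number as a block, 6 genes were called (3 higher, among them Ifit1 and Oasl2, and 3 lower, among them Penk and Tmem255a) and 6 lists, the sixth being immediate early genes, and 4 genes with block and length offsets together. Across all genes the numbers did not pair the samples: deviations of libraries with the same number correlated at -0.0793, 0.0249 and -0.0692, and 0 of 6 libraries correlated best with their own number. Such a correlation cannot exclude a step shared by number that moves only some genes. Levels of immediate early genes ranked alike by number (CFA 5.19, 6.32 and 6, saline 5.70, 6.23 and 6.20). Those of interferon-stimulated genes did not (CFA 3.24, 3.40 and 4.33, saline 3.06, 0.99 and 2.78). Whether pairing by number exists stays open.

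The count of called lists was 5 under RLE, library-size scaling, length offsets and the microglia covariate, 3 with at least 5 CPM in 3 libraries (29 lists tested, layer 6b markers not among them), 8 with the striatal covariate (the striatal list itself not tested; added were immediate early genes at -0.686 against -0.177, inhibitory 0.708, oligodendrocyte 0.276 and precursor markers 0.725, and microglia markers were at 0.746), 0 with an estimated correlation or fry, and 4 to 17 when 1 library was left out. Medians do not move with the correlation used: 0.921 for interferon-stimulated genes, -1.01 for striatal, 0.481 for astrocyte, -0.664 for layer 6b and 0.489 for microglia markers, none past the threshold with an estimated correlation or fry. Calls were also lost for microglia markers with at least 5 CPM in 3 libraries (0.543), and with the microglia covariate for layer 6b (-0.473) and astrocyte markers (0.195). Leaving out 1 library gave 0.774 to 1.56 for interferon-stimulated genes and -1.34 to -0.356 for striatal markers, both past the threshold each time, and 0.254 to 0.601 for astrocyte, -0.89 to -0.418 for layer 6b and 0.275 to 0.866 for microglia markers. Lists that reversed and were called were ribosomal proteins (0.207 without saline replicate 1, against -0.163 without CFA replicate 2 and -0.141 without saline replicate 3), oxidative phosphorylation (-0.16 without saline replicate 3, against 0.226 without saline replicate 1 and 0.109 without CFA replicate 1) and oligodendrocyte markers with the microglia covariate (-0.373), which also called neuromodulator receptors (0.201) and ribosomal proteins (-0.224). Cytoplasm-rich transcripts (-0.184 to 0.0984) were called at -0.184 without saline replicate 3. For them the direction given by camera changed, but the median was already -0.00352 with all libraries. The cause was not tested.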

Other observations

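The second interferon and striatal lists and the covariates were chosen after the main results were seen, and the tests of other splits for the counts of genes and lists, the reading of striatal members under 10 CPM and the t interval between libraries, were chosen after their results were seen. A second list of interferon-induced genes, sharing no member with the first and none of the genes with the smallest p, was also higher in CFA libraries. Of 35 tested members 33 had a positive log2 fold change and 10 an unadjusted p under 0.05, all higher, with a median of 0.743. Among them were the antiviral GTPase Mx2 (2.88), the RNA sensor Ddx58 (2.23), the peptide transporter subunit Tap1 (1.54) and Rtp4 (1.64), chosen after their values were seen (log2 fold changes in parentheses). The camera p was 2.68e-13 with the preset correlation and 0.0489 with an estimated correlation. The mean log2 CPM of this list was 2.95, 2.79 and 3.61 in CFA and 2.66, 1.28 and 2.24 in saline libraries (two-sided exact permutation p = 0.1, the smallest possible). As a hypothesis, this is consistent with a wider interferon response in the CFA libraries, though both lists are lowest in saline replicate 2 and are not independent of each other.

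Several genes called by other tools had 0 counts in every saline library. Slco2b1, an organic anion transporter, had 68, 52 and 5 counts in the CFA libraries, Irgm2, an interferon-induced GTPase, had 26, 6 and 49, and Nlrc5, a regulator of MHC class I genes, had 11, 15 and 12. DESeq2 called the first pair, with adjusted p-values of 0.00471 and 0.0278, and edgeR's likelihood ratio test called Nlrc5, with an adjusted p of 0.00515. These genes were chosen after their values were seen.

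The higher interferon-stimulated genes may come from other cells in the sort, from RNA differences between libraries, or from a response of the neurons. Leaving out saline replicate 3, the library with the largest shares of Malat1, Meg3 and Snhg11, left a median of 1.25 in place of 0.921. Its interferon level of 2.78 was above the saline mean of 2.28, so the level difference had to grow without it. The difference thus did not rest on that library alone. Since the rise followed from its level, it is no separate test of RNA composition, and it does not cover saline replicate 2. All 6 libraries had Y-linked transcripts with Xist under 1 CPM, which argues against sex as a cause. CFA replicate 3 did have 10 counts of Xist (0.961 CPM). Other cells stay open. The test required a marker median of 0.461, a part of the interferon median. Medians of microglia (0.489) and astrocyte markers (0.481) met this rule, written before the test, and that of vascular and meningeal markers (-0.603) did not. Bounds over members were 0.148 to 0.688, -0.0399 to 0.579 and -1.11 to -0.137, but such bounds leave out the spread between libraries. The 95% t intervals of the level differences were -0.612 to 1.81 for microglia and -0.155 to 1.08 for astrocyte markers. The vascular list, whose 5 members lie near the floor, had a level difference of -0.203 with an interval of -1.25 to 0.846. With the microglia level as a covariate the interferon median was 0.926 and past the camera threshold at the preset correlation, but without the covariate the list already had an adjusted p = 0.654 with an estimated correlation in camera, and how much of the difference comes with microglia stays open. Of the 10 splits of the libraries into 3 and 3, only 1, the real one, gave a camera p as small (8.99e-11, against 7.02e-07 for the next), and 10 splits are too few for a share under 0.05.

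Lower striatal projection neuron markers may reflect fewer striatal nuclei caught with the mPFC dissection. A second list of 21 striatum-enriched genes had a median of -0.257 (-0.372 to -0.0801), short of the -0.503 that the test required. Its lower bound lay above -0.503, so the rule written before this list was run counts against fewer striatal nuclei. Such bounds over members leave out the spread between libraries. After that result the list was split at 10 CPM, since cortical neurons may also express the 14 members at 10 CPM or more (median -0.244). That expression was not measured here. The first list also holds such members, with Drd1 at 84.6 CPM in CFA and 126 CPM in saline libraries and Meis2 at 112 and 120 CPM. The 7 members under 10 CPM had a median of -1.08 (-1.76 to 0.433), close to the -1.01 of the first list but with bounds on both sides of 0. Dissection and a change in the neurons therefore cannot be told apart here, and no other biological explanation was tested.

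The libraries hold a structure other than treatment. The real split called 0 genes and 437 at an unadjusted p under 0.05, whereas the split of CFA replicates 1 and 3 with saline replicate 3 against the rest called 10 genes and had 1406. The other 8 splits called 0 genes too, so a comparison with the real count of 0 decides nothing, while 6 of the 10 splits, the real one included, had at least 437 genes at an unadjusted p under 0.05. For lists the real split called 5 and the highest other 11, 8 of the 10 splits, the real one included, called at least 5, and 10 splits are too few for a share under 0.05. The interferon median was as large in 2 of the 10 splits, at 0.921 for the real one and 0.957 for CFA replicate 1 with saline replicates 2 and 3 against the rest.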
